A study of Mus musculus with 16 samples.

How the data were processed

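RNA-seq of polyadenylated RNA was analysed for 12 libraries, 3 in each of 4 groups: FoB and GCB from WT and from cKO mice. Libraries were made by the Nextera method and sequenced on a HiSeq2500, per the labels. The 4 ATAC-seq samples of the series were not analysed here, since the comparisons concern gene expression.

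The deposited gene table holds raw read counts per Ensembl gene, made by the authors, for 25640 genes. A second deposited table repeats the same counts for 10518 genes that the authors kept by a rule not given in the sources used here. The authors also deposited log2 CPM for these genes, and their values lay within 0.00397 of TMM-scaled log2 CPM for genes with every count at 100 or more, and up to 0.105 from unscaled log2 CPM. The authors' table of results holds log2 fold changes of cKO over WT with p-values and false discovery rates (FDR). Per the submitters' processing notes, mm10, Bowtie2, MACS2 and edgeR were used. Their versions, the read counter, the annotation, strand use and the edgeR design are not given in the sources used here. Genes that overlap others, host noncoding RNAs or have close paralogs therefore carry an uncertain share of reads.

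Gene symbols came from the reference tables for 25607 gene IDs, and coordinates from RefSeq on the same genome build, GRCm38.p6 (mm10). Total counts ran from 23349512 to 26967943 per library, and no library was a copy of another (0 identical pairs). The low-count filter (filterByExpr on the 4 groups) kept 13708 genes and left out 11932, and the kept genes held 99.93% to 99.96% of each library's counts.

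Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM factors and the quasi-likelihood F test on group means of all 12 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 8 residual degrees of freedom, and the biological coefficient of variation was 0.266. The comparisons were cKO against WT in GCB and in FoB, GCB against FoB in WT and in cKO, and the difference of the genotype effects (GCB minus FoB). Expression values are TMM-scaled CPM, as mean ± SD of 3 libraries, and log2 fold changes are given ± standard error. Set tests used camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, for lists with at least 5 tested genes, adjusted over the lists of a comparison.

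Lists, comparisons, alternatives and the rule for naming genes were fixed before the data were examined. Rock2 and Rock1 were named first. In the genotype comparisons the rule took the 10 higher and 10 lower genes by size of log2 fold change, among those past the test with a mean of at least 5 CPM in the higher group and no overlap of replicates. Where fewer than 5 passed, it took the 10 smallest p-values. It took 8 higher and 8 lower genes for the cell types in WT and up to 10 for the difference. Immunoglobulin and T cell receptor segments were given as a group. From each list it named the members with the smallest adjusted p.

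The lists covered cholesterol synthesis, sterol sensing and uptake, LXR targets, fatty acid synthesis, the germinal center B cell, naive follicular, dark zone, light zone, memory precursor and plasma cell programs, and positioning and adhesion. They also covered SRF targets, S phase, G2/M, interferon-stimulated genes, IRF and ETS factors, the integrated stress response, glycolysis, oxidative phosphorylation, ribosome biogenesis, ribosomal proteins, B cell receptor signaling, MHC class II, apoptosis, DNA repair, immediate early and heat shock genes and mitochondrially encoded genes. Marker lists covered T cells, NK cells, macrophages, dendritic cells, neutrophils, erythroid cells, platelets, stroma, marginal zone and B-1 cells, and sex-linked genes. Of the lists 35 had enough genes to test.

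Replicate numbers were checked for pairing before calls were compared. After each group's mean was taken off, the 18 pairs of libraries of the same number in different groups correlated across genes at 0.478 to 0.753 (median 0.584), and the 36 pairs of different numbers at -0.654 to 0.0952 (median -0.304). The closest library in another group had the same number for 12 of 12 libraries. The numbers thus pair the samples, and the fit with the number as a block had a coefficient of variation of 0.114 and 6 residual degrees of freedom. Libraries of the same group had Spearman correlations of 0.972 to 0.988.

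The test was tried on simulated counts with 100 genes changed at a log2 fold of 1 and another 100 at 2 in the GCB comparison. Each count of false calls covers both sizes together. Counts drawn without a block gave 46% of genes recovered at a log2 fold of 1 and 88% at 2, with 4 false calls, and the block fit gave 38% and 87% with 6. Counts drawn with a block gave 88% and 98% with 25 false calls in the block fit. Those 25 were a larger share of its calls than the threshold of 0.05 allows. Without the block in the fit the same counts gave 38% and 88% with 0 false calls. A raised list ranked 1 of 35, with 0 other lists past the test. Each gene was drawn independently around its fitted means, so correlation between genes beyond the replicate effects was absent. The trial thus could not show false list calls that such correlation makes.

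Alternatives were RLE and upper quartile factors, no filter, a stricter filter (5 CPM in 3 libraries), the authors' filtered genes, DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, only the groups compared, the replicate block, removal of immunoglobulin and T cell receptor genes, stricter thresholds, and each library left out in turn. Set tests were also run with an estimated correlation, with fry, with the block and with RLE factors. Added after the data were seen were the block with DESeq2, with limma-voom or with an estimated correlation, the block without cKO GCB 1 or WT FoB 1, the naming rule on the block fit and a list of p53 targets.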

Results

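Polyadenylated RNA was sequenced from follicular B cells (FoB) and germinal center B cells (GCB) sorted from the spleens of C57BL/6 mice, 7 days after immunization with 100 µg of the hapten conjugate NP-CGG in alum. The mice were 10 weeks old and homozygous for floxed Rock2, which encodes a serine-threonine kinase that acts on the cytoskeleton. WT mice lacked Cre, and conditional knockout (cKO) mice carried CD23-Cre, which is active in B cells from the stage at which CD23 appears. Each of the 4 groups (WT FoB, cKO FoB, WT GCB and cKO GCB) held 3 libraries with replicate numbers 1 to 3. Total counts per library ran from 23349512 in WT FoB 3 to 26967943 in cKO FoB 1. The replicates are not stated to be separate animals, so the p-values below measure only the spread between these samples.

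Cell type separated the libraries first. The first principal component of log2 CPM (read counts scaled to library size) held 71.8% of the variance and parted the 6 FoB from the 6 GCB libraries. The second component held 12.2% and followed the replicate number, with the 4 libraries of number 2 between -60.0 and -34.1 and the other 8 between 13.7 and 32.4. The libraries of number 2 also carried more mitochondrially encoded RNA (3.72% to 5.50% of counts, against 1.05% to 2.95% elsewhere). Xist, the RNA that silences an X chromosome in female cells, was at 42.0 to 234 CPM in number 2 and at 188 to 763 CPM in the others. On the first component WT FoB 1 lay at -68.2 (the other FoB libraries at -83.8 to -79.8), and cKO GCB 1 lay at 59.5 (the other GCB libraries at 78.6 to 91.8). Both libraries thus lay nearer to the opposite cell type than their replicates did.

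**Figure D1:**
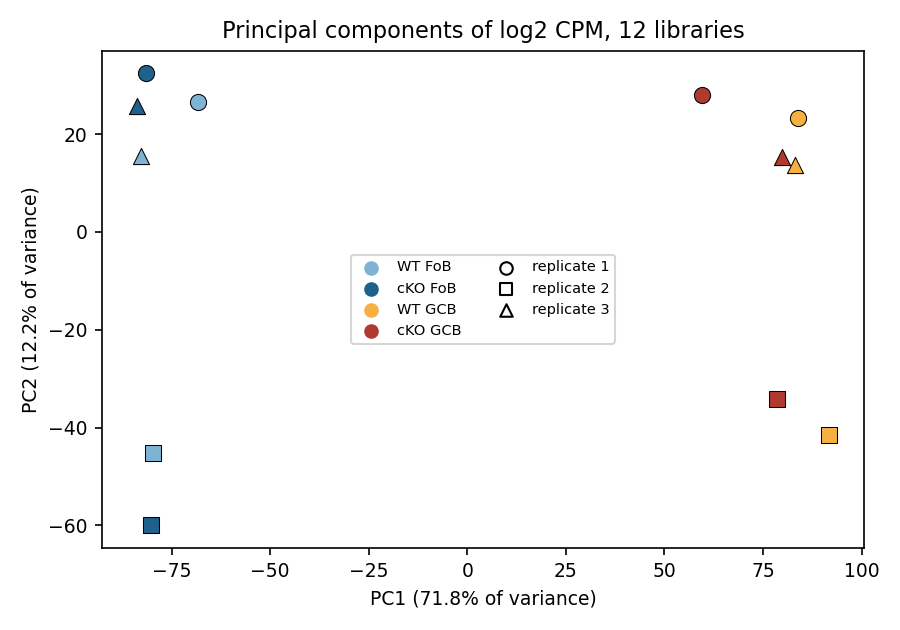
First and second principal components of log2 CPM over the tested genes, 1 point per library, with group by colour and replicate number by marker shape. FoB and GCB libraries separate on the first component (71.8% of the variance), and the libraries of replicate number 2 separate from the others on the second (12.2%).

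Rock2, the targeted gene (ENSMUSG00000020580, mm10 chromosome 12, 16894978 to 16988274), was lower in all cKO libraries than in any WT library of the same cell type. In GCB it measured 166 ± 28.4 CPM in WT and 114 ± 19.7 CPM in cKO (mean ± SD, n = 3), a log2 fold change of -0.54 ± 0.18 (± standard error). In FoB it measured 137 ± 12.2 CPM in WT and 102 ± 18.4 CPM in cKO, a log2 fold change of -0.42 ± 0.18. Each cKO library lay below the WT library of its number, in 3 of 3 numbers per cell type. Neither difference passed the edgeR test over all genes (adjusted p = 0.563 in GCB and 1 in FoB). With the replicate number as a block, Rock2 fell in GCB (-0.53 ± 0.12, adjusted p = 0.0330). Over its 20 alternatives Rock2 in GCB passed in 3, with adjusted p from 0.00371 to 1. Reads from exons outside the floxed part can remain after deletion, and the counts are per gene. Rock1, the paralog (chromosome 18, 10064401 to 10182251), measured 223 ± 48.9 CPM in WT GCB and 193 ± 41.8 CPM in cKO GCB (-0.21 ± 0.21, adjusted p = 1). Its log2 fold change in FoB was -0.12 ± 0.21 (adjusted p = 1). Reads shared between paralogs are uncertain, and both genes host noncoding RNAs on a strand that the counts may not separate.

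The comparison of cKO with WT GCB asked which genes depend on Rock2 in the germinal center. Dglucy, which encodes a mitochondrial D-glutamate cyclase (ENSMUSG00000021185, chromosome 12, 100779057 to 100872610), rose from 0.782 ± 0.126 to 10.3 ± 1.35 CPM. Its log2 fold change was 3.71 ± 0.21 (adjusted p = 1.05e-05), and WT FoB held it at 16.5 ± 2.59 CPM. Serpine2, a secreted inhibitor of serine proteases, rose from 0.478 ± 0.0497 to 5.23 ± 1.29 CPM (3.44 ± 0.31, adjusted p = 0.000726). Cdkn1a, which encodes the p21 inhibitor of cyclin-dependent kinases, rose from 1.46 ± 0.339 to 9.44 ± 0.993 CPM (2.69 ± 0.26, adjusted p = 0.000973). These 3 genes stayed past the test in each of their 20, 19 and 20 alternatives, with highest adjusted p of 0.00509, 0.0169 and 0.0258.

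The other 7 genes that the naming rule picked were also higher. Inka2, an inhibitor of the kinase PAK4, rose from 1.37 ± 0.174 to 7.56 ± 1.24 CPM (2.46 ± 0.33, adjusted p = 0.0163). Epha2, an ephrin receptor, rose from 1.70 ± 0.319 to 6.72 ± 0.693 CPM (1.98 ± 0.29, adjusted p = 0.0289). Pml, the scaffold of PML nuclear bodies, rose from 28.9 ± 5.45 to 89.4 ± 29.6 CPM (1.63 ± 0.23, adjusted p = 0.0261) and stood at 392 ± 39.4 CPM in WT FoB. Csf1, a macrophage growth factor, rose from 2.75 ± 0.375 to 8.17 ± 1.50 CPM (1.57 ± 0.20, adjusted p = 0.0147). Lgals3bp, a secreted galectin ligand, had a log2 fold change of 1.50 ± 0.23 (adjusted p = 0.0406). Ccnd2, the G1 cyclin D2, rose from 23.4 ± 4.41 to 58.1 ± 14.7 CPM (1.31 ± 0.20, adjusted p = 0.0406), and WT FoB held 193 CPM. Aff1, a scaffold of the super elongation complex, had a log2 fold change of 1.28 ± 0.19 (adjusted p = 0.0311). All 10 genes were higher in cKO in 3 of 3 numbers. These 7 genes lost the call without cKO GCB 1 (adjusted p 0.0696 to 0.189), cKO GCB 2 (0.0519 to 0.165), WT GCB 1 (0.149 to 0.221), WT GCB 2 (0.0507 to 0.158) or WT GCB 3 (0.0993 to 0.186). Ccnd2 also lost it with RLE factors (adjusted p = 0.0523).

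In all, 14 genes rose and 0 fell in cKO GCB among the 13708 tested with edgeR. The count at an unadjusted p under 0.05 was 673. Leaving out cKO GCB 3 gave 58 genes, and leaving out any other GCB library (WT GCB 1, WT GCB 2, WT GCB 3, cKO GCB 1 or cKO GCB 2) gave 5. The groups did not overlap for 8.37% of genes. Chance would give 10% if the libraries were exchangeable, but samples of the same number resemble each other, so 10% is no yardstick here. The remaining 4 called genes were looked at after their values were seen. Phlda3, a repressor of AKT signaling at chromosome 1, 135766085 to 135769134, reached 3.82 ± 0.594 CPM (3.81 ± 0.35, adjusted p = 0.000726). Zmat3, an RNA-binding p53 target, rose from 20.2 ± 1.72 to 46.9 ± 0.891 CPM (1.22 ± 0.13, adjusted p = 0.00304). Adam19, a metalloproteinase, had a log2 fold change of 1.02 ± 0.16 (adjusted p = 0.0460). Phlda3 passed in 19 of 19 alternatives, Zmat3 in 19 of 20 (adjusted p up to 0.0638) and Adam19 in 10 of 20 (up to 0.371). Gm12666, a pseudogene (chromosome 4, 92190743 to 92191750; adjusted p = 0.0261), had 181 counts in cKO GCB and 1 in WT GCB, a ratio of 174 (95% interval 30.9 to 6929). Intervals and floors here cover counting error only.

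**Figure D2:**
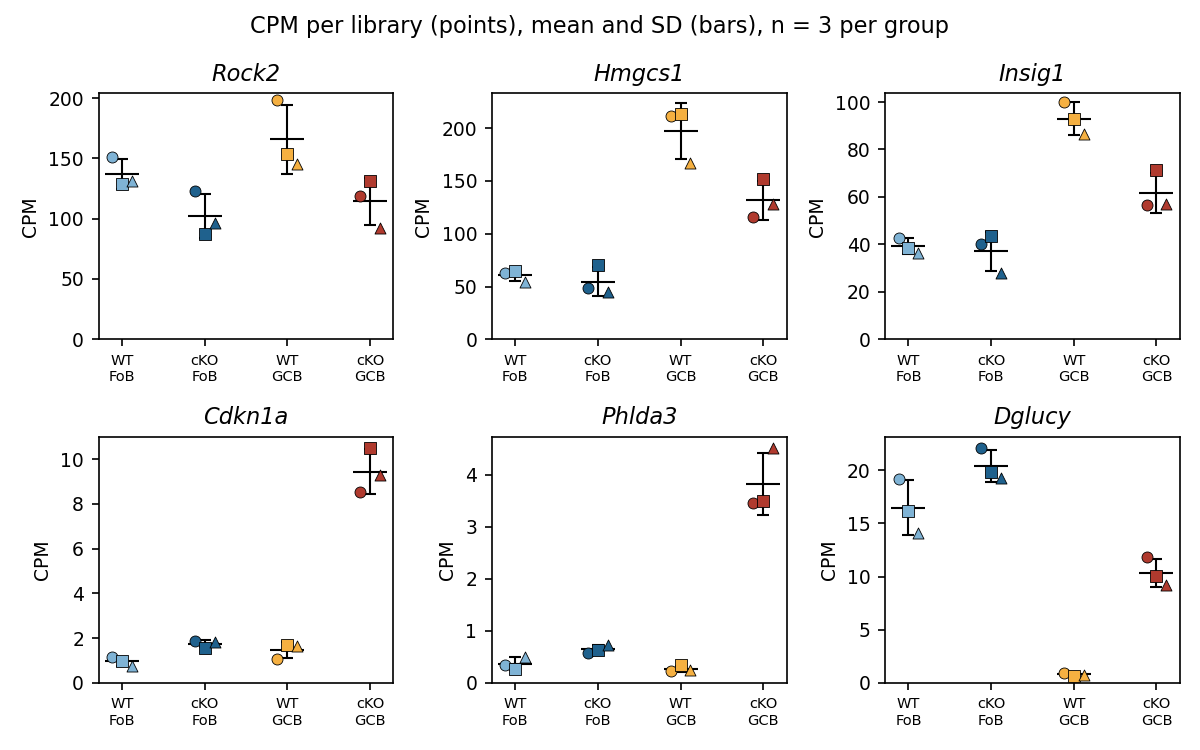
CPM per library (points), group mean and SD (n = 3 per group) of Rock2, Hmgcs1, Insig1, Cdkn1a, Phlda3 and Dglucy. Rock2 lies lower in cKO than in WT within each cell type, and Dglucy is low only in WT GCB (0.782 CPM).

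With the replicate block, 264 genes rose and 29 fell in cKO GCB, including all 14 called without it. Without cKO GCB 1 the same fit called 129 higher and 6 lower. The naming rule, applied to this fit after the data were seen, adds Bhlhe41, a transcription factor of B-1 cells (1.83 ± 0.29, adjusted p = 0.00542), and Fcrl5, an Fc receptor-like protein (1.80 ± 0.28, adjusted p = 0.00506). It also adds S100a10 (1.71 ± 0.22, adjusted p = 0.00162) and Capg, an actin-capping protein (1.64 ± 0.22, adjusted p = 0.00227). Over their 20 alternatives, most of which leave out the block, these 4 genes had highest adjusted p of 0.355, 0.756, 0.546 and 0.380. Genes of sterol supply were among those that fell with the block. Insig1, which holds back the sterol-regulated factor SREBP, measured 93.1 ± 6.79 CPM in WT and 61.6 ± 8.44 CPM in cKO (-0.60 ± 0.11, adjusted p = 0.0152 with the block). Hmgcs1, the synthase that forms HMG-CoA (chromosome 13, 119690351 to 119708260), measured 197 ± 26.5 and 132 ± 18.4 CPM (-0.58 ± 0.11, adjusted p = 0.0152). For Insig1 and Hmgcs1 the highest adjusted p over 20 alternatives was 1. Cd86, a costimulatory ligand, measured 111 ± 12.5 and 81.4 ± 18.8 CPM (-0.47 ± 0.10, adjusted p = 0.0231 with the block and up to 1 over its alternatives). Other lower genes by the rule were Hbb-bh1 (-1.16 ± 0.28), 9930012K11Rik (-0.68 ± 0.16), Igf2bp3 (-0.58 ± 0.13), Cdkl1 (-0.53 ± 0.12) and Atp8a1 (-0.46 ± 0.09). Igf2bp3 and Atp8a1 overlap other genes and Cdkl1 hosts a noncoding RNA, so their counts are uncertain.

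Cholesterol synthesis and cell positioning are themes of the study's title, so their lists, written before the data were examined, are not independent evidence. The cholesterol list was lower as a group in cKO GCB, with 21 of 22 genes below 0 and a median log2 fold change of -0.33 (camera adjusted p = 4.43e-09). The adjusted p was 0.156 with an estimated correlation. None of its genes passed singly, over all genes or adjusted over the list alone (0 genes). Hmgcs1 stood at -0.58 ± 0.19 (adjusted p = 0.476). Fdft1 (-0.45 ± 0.16, adjusted p = 0.660) acts at the committed step that forms squalene. Sqle (-0.45 ± 0.18, 0.815) and Lss (-0.33 ± 0.13, 0.818) act from squalene onward, and the Nsdhl demethylation step stood at -0.41 ± 0.20 (1). With the block 7 genes fell over all genes, among them Hmgcs1, Cyp51, Msmo1, Nsdhl, Fdft1 and Sqle, and 12 adjusted over the list alone. The median difference was -0.41, -0.33 and -0.25 in numbers 1, 2 and 3 of GCB, against -0.14, 0.09 and -0.10 in FoB. WT GCB expressed the list above WT FoB, as given below, so the difference in cKO pointed towards the FoB level.

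**Figure D3:**
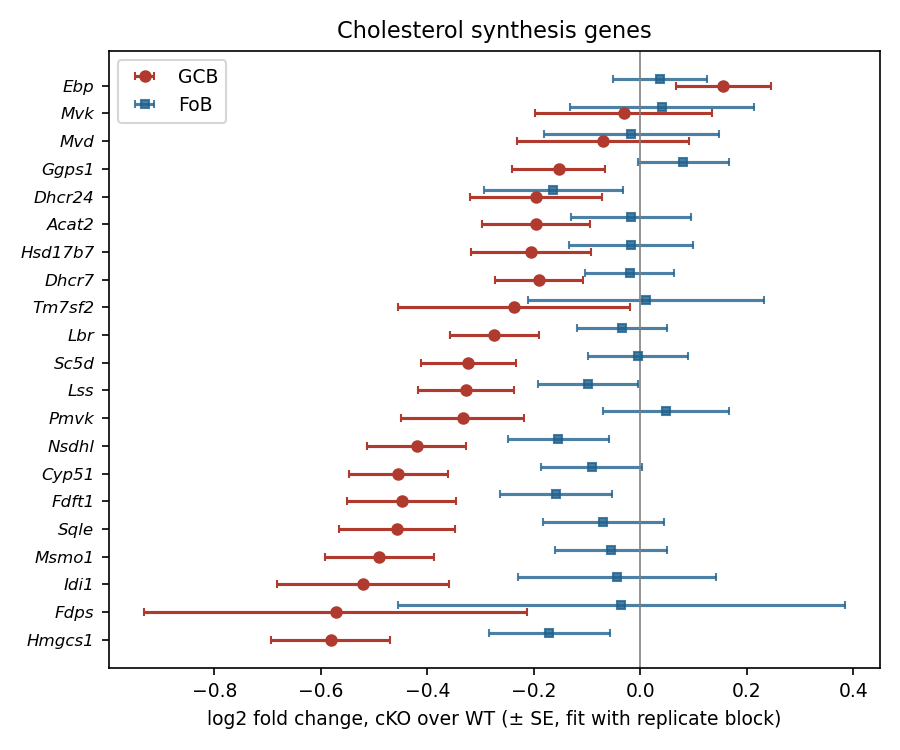
Log2 fold change of cKO over WT (± standard error, fit with the replicate block) for cholesterol synthesis genes in GCB and in FoB. In GCB every value shown except that of Ebp lies below 0, with Hmgcs1 at -0.58.

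Related lipid lists were less uniform. Fatty acid synthesis was lower as a group (10 of 12 below 0, median -0.15, camera adjusted p = 0.0122; 0.343 with an estimated correlation), with the desaturase Fads2 at -0.56 ± 0.31 and Acsl3 at -0.50 ± 0.29. That call was lost without WT GCB 2 (0.158), cKO GCB 1 (0.0888) or cKO GCB 3 (0.0599). Sterol sensing and uptake did not pass (camera adjusted p = 0.0763, median -0.04), although 2 genes passed when adjusted over the list alone, Insig1 among them. The LXR list, which drives sterol efflux, did not pass (camera adjusted p = 0.230, median -0.16). Its Abca1 and Abcg1, both efflux transporters, stood at -0.42 ± 0.21 and 0.50 ± 0.27.

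The naive follicular list was higher as a group in cKO GCB, with 13 of 14 genes above 0 and a median of 0.70 (camera adjusted p = 1.08e-10). The adjusted p was 0.194 with an estimated correlation, and 8 genes passed when adjusted over the list alone. Gpr183, the oxysterol receptor that guides B cells to the follicle's rim, measured 10.4 ± 2.61 CPM in WT and 26.0 ± 4.99 CPM in cKO (1.33 ± 0.22, adjusted p = 0.0548). The chemokine receptor Ccr6 stood at 1.59 ± 0.27 (0.0548), the survival factor Bcl2 at 1.18 ± 0.21 (0.0674) and Ccr7, which draws cells to the T zone, at 1.41 ± 0.30 (0.146). All 4 passed with the block (adjusted p 0.000352, 0.00249, 0.00241 and 0.00677), with highest values of 0.415, 0.430, 0.534 and 0.640 over 20 alternatives. WT FoB held far more of Gpr183 (109 CPM) and Ccr6 (207 CPM). The list's median difference was largest in number 1, which holds cKO GCB 1 (1.14, against 0.59 and 0.45 in numbers 2 and 3). Memory precursors shared this pattern (10 of 12 above 0, median 0.84, camera adjusted p = 3.13e-08; 0.156 with an estimated correlation). Of the memory genes 7 passed when adjusted over the list alone, among them the cytokine receptor Il9r (1.59 ± 0.34, adjusted p = 0.144) and the costimulatory Cd80 (4.12 CPM in WT and 10.1 CPM in cKO, adjusted p = 0.369).

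Lists of other cell types moved in part with the naive genes. The T cell list was higher (14 of 15 above 0, median 1.08, camera adjusted p = 4.18e-08; 0.194 with an estimated correlation), with 2 genes past adjusted over the list alone. Its leading genes were Cd5, which B-1 cells also carry (1.50 and 2.92 CPM in WT and cKO; 0.96 ± 0.28, adjusted p = 0.358), and the transcription factor Tcf7 (1.33 ± 0.40, adjusted p = 0.388). The T cell receptor component Cd3e measured 0.199 CPM in WT GCB, 0.570 in cKO GCB and 1.32 in WT FoB. The NK list was higher (9 of 9 above 0, median 0.75, camera adjusted p = 0.000579; 0.371 with an estimated correlation), with Klrk1 at 1.19 ± 0.59 and Nkg7 at 0.81 ± 0.47. The marginal zone and B-1 list was higher (11 of 13 above 0, median 0.42, camera adjusted p = 0.000124; 0.194 with an estimated correlation), with 3 genes past adjusted over the list alone. Bhlhe41 led it (1.86 ± 0.34, adjusted p = 0.0759), and Plac8 (1.55 ± 0.36, adjusted p = 0.186) is also abundant in WT FoB (603 CPM).

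**Figure D4:**
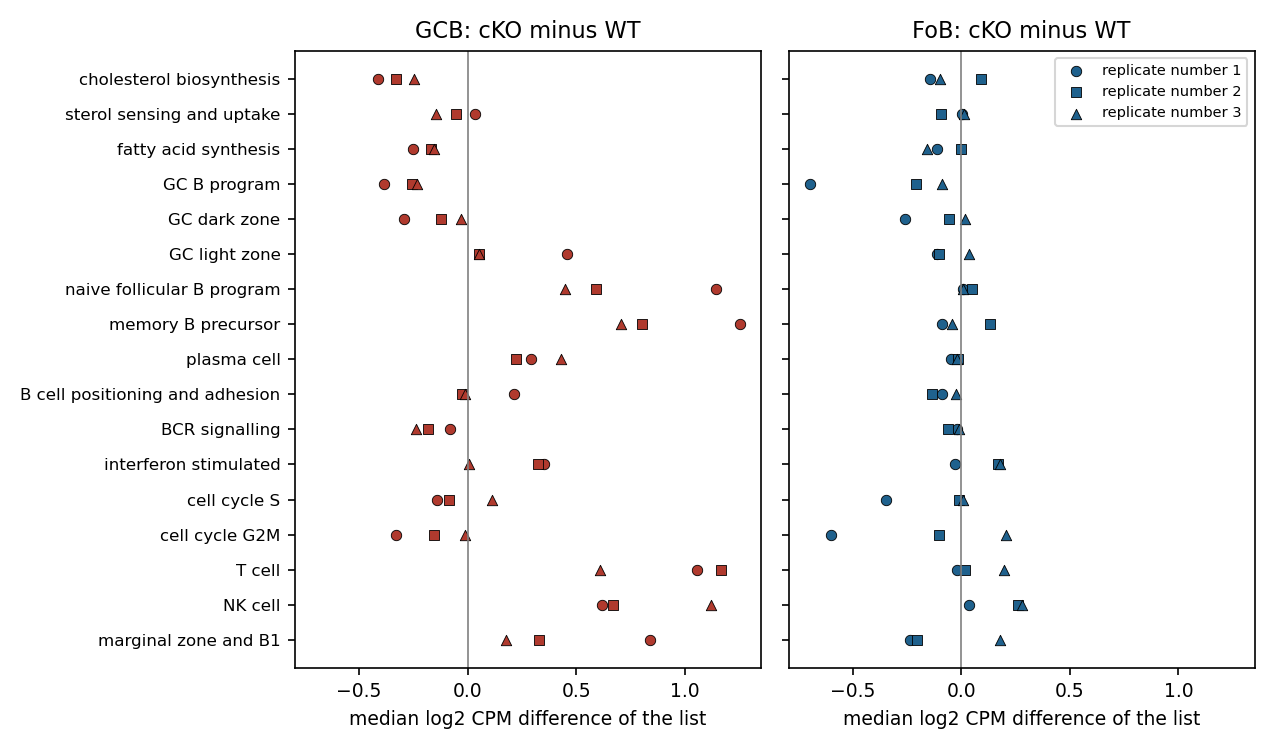
Median log2 CPM difference of cKO minus WT per gene list and replicate number, in GCB and in FoB. In GCB the naive list lies at 1.14, 0.59 and 0.45 and the cholesterol list at -0.41, -0.33 and -0.25 in numbers 1, 2 and 3.

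Differentiation and positioning lists split. The plasma cell list was higher (median 0.32, camera adjusted p = 3.51e-05; 0.194 with an estimated correlation). Of its 14 genes 3 passed adjusted over the list alone: the chaperone Fkbp11 (1.85 ± 0.36, adjusted p = 0.0998), Irf4 (0.90 ± 0.19, 0.146) and Prdm1, the master regulator of plasma cells (1.23 ± 0.27, 0.152). The positioning list passed as higher (camera adjusted p = 0.00748; 0.343 with an estimated correlation) with a median of 0.04 and a mean of 0.29 over 29 genes. Only 15 lay above 0, led by Gpr183, Ccr6, Ccr7 and the G protein regulator Rgs16 (1.87 ± 0.48, adjusted p = 0.267), followed by the integrin chain Itgb7 (0.70 ± 0.25, 0.650). It had 5 genes past adjusted over the list alone, and Gpr183, Ccr6 and Ccr7 are on the naive list too. With the block the list did not pass (adjusted p = 0.100; 0.0013 to 0.640 over its 10 alternatives). It was also lost without WT GCB 1 (0.0644) or cKO GCB 2 (0.0609).

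Germinal center genes were mostly lower. The germinal center B cell list had 17 of 18 genes below 0 and a median of -0.23 (camera adjusted p = 0.000629; 0.224 with an estimated correlation), with 0 genes past adjusted over the list alone. The death receptor Fas stood at -0.40 ± 0.20, Basp1 at -0.40 ± 0.25, the repressor Bcl6 at -0.36 ± 0.23, Nuggc at -0.58 ± 0.45, Bach2 at -0.26 ± 0.20 and the confinement mediator Gna13 at -0.20, each with an adjusted p of 1. B cell receptor signaling was lower by less (19 of 20 below 0, median -0.15, camera adjusted p = 0.000408; 0.194 with an estimated correlation), with the kinase Btk at -0.24 ± 0.13 and the inhibitory Fcgr2b at -0.30 ± 0.16. The dark zone list did not pass (camera adjusted p = 0.230, median -0.12). Its Polh, an error-prone polymerase, stood at -0.35 ± 0.18, and the dark zone receptor Cxcr4 at -0.22 ± 0.30. The light zone list passed as higher (16 of 23 above 0, median 0.21, camera adjusted p = 0.0475, and 0.467 with an estimated correlation). Its median difference was 0.46 in number 1, against 0.05 and 0.05 in numbers 2 and 3. Ccnd2 and Irf4 passed adjusted over the list alone (2 genes), while the light zone marker Cd86 stood at -0.45 ± 0.22. This call was lost with the block (0.0553; 0.00478 to 0.640 over 10 alternatives), and without WT GCB 1 (0.425), WT GCB 2 (0.169), cKO GCB 1 (0.258) or cKO GCB 3 (0.149).

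Cell cycle, repair and growth lists moved little. The G2/M list had 24 of 24 genes below 0 with a median of -0.16 (camera adjusted p = 0.0475; 0.793 with an estimated correlation), with Nusap1 at -0.23 ± 0.30 and Kif23 at -0.24 ± 0.37. It was lost with the block (0.128; 0.0211 to 0.849 over 10 alternatives) and without WT GCB 1 (0.0570), WT GCB 2 (0.340), cKO GCB 1 (0.268) or cKO GCB 3 (0.0804). DNA repair genes were lower (18 of 23 below 0, median -0.11, camera adjusted p = 0.0475; 0.587 with an estimated correlation), led by Polh and the endonuclease Apex2 (-0.24). That call was lost without WT GCB 1 (0.256), WT GCB 2 (0.272), cKO GCB 1 (0.258) or cKO GCB 3 (0.134). Ribosome biogenesis was higher (16 of 18 above 0, median 0.12, camera adjusted p = 0.0475; 0.371 with an estimated correlation), with Rrp12 at 0.39 ± 0.17 and Polr1b at 0.27 ± 0.15. It was lost without WT GCB 1 (0.135), WT GCB 3 (0.308), cKO GCB 2 (0.298) or cKO GCB 3 (0.278). With RLE factors the light zone, G2/M, DNA repair and dendritic cell lists stood at 0.0501 and ribosome biogenesis at 0.0508, none of them past the test.

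Innate and immune-response lists gave smaller or library-dependent values. Interferon-stimulated genes were higher (17 of 22 above 0, median 0.33, camera adjusted p = 0.00298; 0.343 with an estimated correlation), with the GTPases Gbp2 at 0.71 ± 0.28 and Mx1 at 1.75 ± 0.86. That call was lost without cKO GCB 1 (0.106) or cKO GCB 2 (0.0570). The dendritic cell list was higher in its test (4 of 8 above 0, median 0.16, camera adjusted p = 0.0475; 0.371 with an estimated correlation), with the transcription factor Zbtb46 at 1.72 ± 0.39 and the integrin Itgax at 1.12 ± 0.37 (2 genes past adjusted over the list alone). It was lost with the block (0.127; 0.00945 to 0.534 over 10 alternatives) and without WT GCB 1 (0.135), WT GCB 3 (0.187) or cKO GCB 2 (0.474). The neutrophil list was lower (6 of 6 below 0, median -2.29, camera adjusted p = 0.0160; 0.399 with an estimated correlation) from few reads, with the granule gene Ngp at 1.36 and 0.255 CPM and Camp with 3 counts in cKO GCB. It was lost without WT GCB 1 (0.135), WT GCB 2 (0.350), cKO GCB 1 (0.134) or cKO GCB 3 (0.0804).

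The remaining lists did not pass. SRF targets had a camera adjusted p of 0.888 (median 0.05, mean -0.01, test lower), with Vcl at 0.50 ± 0.27 and Fos at -1.08 ± 0.68. Apoptosis regulators had an adjusted p of 0.414 (median -0.07, mean 0.19, test higher), with the p53 targets Bax at 0.84 ± 0.24 and Bbc3 at 1.68 ± 0.56. S phase genes had a median of -0.02 (0.454), with Rpa2 at 0.13 and Slbp at -0.14. Immediate early genes had a median of -0.18 (0.151), with Klf6 at -0.48 ± 0.26. The IRF and ETS factors stood at 0.559 (median -0.08, mean 0.01, test lower), with Irf4 past adjusted over the list alone, and the integrated stress response at 0.843 (median 0.01, mean -0.05, test lower), with Sesn2 at 0.63 ± 0.21. Glycolysis had a median of 0.08 (0.237), with Slc2a3 at 0.25 ± 0.12 and Hk2 at 0.28. Oxidative phosphorylation (0.639, median 0.01, test lower, Atp5c1 at -0.10) and ribosomal proteins (0.571, median 0.0022, mean -0.0010, test lower, Rps3 at -0.13) stayed near 0. MHC class II genes had a median of -0.05 (0.296), with H2-Ob at -0.27 ± 0.20 and Rfx5 at -0.18. Macrophage genes had a median of 0.02 (0.625), with Itgam at 1.80 ± 0.47. Erythroid genes had a median of 1.04 (0.888), with Hba-a1 at 1.40 ± 0.95. Mitochondrially encoded genes had a median of -0.29 (0.260, and 0.0194 with the block; 0.640 with block and estimated correlation), with mt-Nd6 at -0.44 and mt-Nd1 at -0.33. Too few genes were measured to test platelet genes (Itga2b at 0.35), stroma (median 0.11) and sex-linked genes (Xist at 0.09). Of 251 immunoglobulin and T cell receptor segments, 0 were called by edgeR, and with the block 17 rose and 2 fell.

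In FoB the same comparison asked what Rock2 loss did in resting cells. edgeR called 0 genes in either direction, with 95 at an unadjusted p under 0.05 and a smallest adjusted p of 0.554. DESeq2 called 4, the edgeR likelihood ratio test 6 and limma-voom 0. The groups did not overlap for 2.20% of genes (10% by chance if libraries were exchangeable). Genes among the 10 smallest p-values are given as values only. Parm1, a mucin-like protein (1.74 ± 0.544 CPM in WT, 0.464 ± 0.258 in cKO), stood at -1.94 ± 0.34 (adjusted p = 0.554). Several were germinal center genes at low level. Gcsam, a regulator of germinal center cell motility, measured 2.22 ± 2.68 CPM in WT FoB and 0.190 ± 0.147 in cKO FoB (-3.58 ± 0.89, adjusted p = 1). S1pr2, the receptor that confines cells to the germinal center, stood at -1.50 ± 0.37, and the nuclear GTPase Nuggc at -2.06 ± 0.55. The SD of Gcsam in WT exceeded the mean. Gm12666 had 54 counts in cKO FoB and 0 in WT FoB, at least 17.0-fold higher against a floor of 3 counts per group (adjusted p = 0.554). Gm4815 had 70 and 11 counts, a ratio of 6.00 (95% interval 3.16 to 12.6). The others were Cobl (-2.56 ± 0.63), Trabd2b (-1.66 ± 0.42) and Usp2 (-1.24 ± 0.33). DESeq2 called Parm1 (adjusted p = 0.000161) and Gm12666 (0.00457), and over their alternatives each ran up to 1.

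The germinal center B cell list was lower as a group in cKO FoB (13 of 18 below 0, median -0.31, mean -0.77, camera adjusted p = 2.94e-12; 0.0666 with an estimated correlation). Of its genes 4 passed adjusted over the list alone, and the median difference was largest in number 1, which holds WT FoB 1 (-0.70, against -0.21 and -0.09). The dark zone list was lower, with Gcsam in the lead (median -0.04, mean -0.71, camera adjusted p = 0.00544; 0.208 with an estimated correlation; 2 genes adjusted over the list alone). It was lost with the block (0.119; 0.00583 to 0.834 over 10 alternatives) and without WT FoB 1 (0.0525), cKO FoB 1 (0.100) or cKO FoB 3 (0.0666). The positioning list was lower (median -0.05, camera adjusted p = 0.00544; 0.507 with an estimated correlation) with S1pr2 alone past adjusted over the list, and Cxcr3 at -0.77 ± 0.32. It was lost without WT FoB 2 (0.508), cKO FoB 1 (0.338) or cKO FoB 3 (0.0671).

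Proliferation lists in FoB hung on single libraries. S phase genes were lower (median -0.14, camera adjusted p = 0.00544; 0.813 with an estimated correlation; Mcm3 at -0.20 ± 0.15), but reversed without WT FoB 1 (0.328) and were lost without cKO FoB 2 (0.290) or cKO FoB 3 (0.0743). G2/M genes were lower (median -0.24, camera adjusted p = 0.00706; 0.880 with an estimated correlation; Tpx2 at -0.41 ± 0.33), but higher without WT FoB 1 (2.97e-06) and without cKO FoB 2 (0.407), and lost without cKO FoB 3 (0.0666). Interferon-stimulated genes were higher (19 of 22 above 0, median 0.16, camera adjusted p = 0.000587; 0.507 with an estimated correlation; Ifit1 at 0.56 ± 0.28), a call lost without cKO FoB 2 (0.148). Immediate early genes were lower (15 of 18 below 0, median -0.30, camera adjusted p = 0.000587; 0.507 with an estimated correlation; Atf3 at -1.03 ± 0.54), a call lost without WT FoB 2 (0.0732) or cKO FoB 2 (0.114). The neutrophil list was lower (median -1.05, camera adjusted p = 0.00706; 0.667 with an estimated correlation; S100a8 at -1.57 ± 1.15), a call lost without WT FoB 1 (0.360), WT FoB 2 (0.289), cKO FoB 1 (0.141) or cKO FoB 3 (0.0757). The cholesterol list did not pass (14 of 22 below 0, median -0.02, camera adjusted p = 0.273; Hmgcs1 at -0.15 ± 0.19), nor did the naive list (0.967).

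The comparison of GCB with FoB in WT gives the background against which the genotype effects lie. Gcsam rose from 2.22 to 528 CPM (7.85 ± 0.75, adjusted p = 5.73e-06). Ackr4, a scavenger of chemokines (7.43 ± 0.73), the linker histone H1fx (7.23 ± 1.11), Evc (7.21 ± 0.56), the ETS factor Ehf (7.20 ± 0.59) and Lhfpl4 (6.86 ± 0.63) also rose. The sodium channel gene Scn11a had 600 and 2 counts in GCB and FoB, a ratio of 304 (95% interval 83.8 to 2517). Fcgrt, the neonatal Fc receptor, fell from 45.6 ± 12.2 to 1.21 ± 0.544 CPM (-5.22 ± 0.35), and Plaur, the urokinase receptor, from 65.5 ± 8.68 to 1.93 ± 0.418 CPM (-5.08 ± 0.34). Pdk2, a brake on pyruvate use (-6.29 ± 0.48), Ptpn14 (-5.75 ± 0.51), Irgc1 (-5.74 ± 0.70), Gad1 (-5.73 ± 0.63) and Gm15448 (-5.35 ± 0.54) fell too, and Ptpn14 overlaps another gene. Wfdc17 had 728 counts in FoB and 4 in GCB, a ratio of 180 (95% interval 69.8 to 661). These genes had edgeR adjusted p from 5.5e-07 to 0.000217 and stayed past in each of 10 alternatives. Rock2 stood at 0.27 ± 0.18 (adjusted p = 0.238) and Rock1 at 0.34 ± 0.21 (0.210). Rock1 passed with the block (0.32 ± 0.10, adjusted p = 0.00904; 0.00904 to 0.531 over its alternatives).

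In WT 3512 genes rose and 3122 fell (52.9% higher), and the groups did not overlap for 56.3% of genes (10% by chance if libraries were exchangeable). Upper quartile factors moved the median of all genes by -0.15 on the log2 scale and turned the majority, with 2972 higher and 3766 lower. RLE factors gave 3432 and 3179. Of the immunoglobulin and T cell receptor segments 13 rose and 144 fell. In cKO 3402 rose and 2982 fell, the groups did not overlap for 53.6% of genes, and 12 segments rose and 125 fell. Upper quartile factors shifted the median there by -0.12 and gave 2983 higher and 3574 lower. The genotypes shared 3119 higher and 2631 lower genes, where chance would give 872 and 679, and 1 gene was called in opposite directions. Across genes the log2 fold changes of the genotypes correlated (Pearson 0.941, Spearman 0.949), and genes are not independent replicates.

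Among the lists, cell cycle and germinal center genes were higher in WT GCB and naive genes lower. All 24 G2/M genes rose (median 4.18, camera adjusted p = 2.18e-14; 0.281 with an estimated correlation; Aurka 4.09 ± 0.23, Cdc20 4.38 ± 0.29), as did 21 of 22 S phase genes (median 2.78, 1.98e-13; 0.174 with an estimated correlation; Mcm3 2.74 ± 0.16, Mcm5 2.81 ± 0.17). The germinal center list had 15 genes higher and 1 lower (median 4.70, 8.64e-08; 0.101 with an estimated correlation), among them Basp1 (6.17 ± 0.32), S1pr2 (6.62 ± 0.40), Plxnb2 (4.27 ± 0.23) and Fas (3.71 ± 0.22). The dark zone list had 8 of 10 higher (median 3.10, 0.000172; 0.101 with an estimated correlation; Polh 4.02 ± 0.21, Ccnb1 4.72 ± 0.40). The light zone list was lower (2 higher, 14 lower, median -1.12, 0.00606; 0.315 with an estimated correlation), since Ccnd2 (-3.04 ± 0.22), Egr3 (-3.39 ± 0.26) and Cd40 (-1.58 ± 0.13) were more abundant in FoB, while Traf1 rose (1.63 ± 0.22). All 14 naive genes fell (median -3.73, 1.58e-10; 0.197 with an estimated correlation), with Bcl2 at -3.76 ± 0.23, the quiescence factor Klf2 at -4.01 ± 0.29 and Ccr7 at -5.02 ± 0.34. Memory genes were lower (3 higher, 8 lower, median -2.81, 0.00621; 0.315 with an estimated correlation).

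Of the cholesterol genes 15 rose and 1 fell, or 17 and 1 adjusted over the list alone (median 1.35, camera adjusted p = 1.21e-05; 0.197 with an estimated correlation). Acat2, the first enzyme of the pathway, stood at 2.33 ± 0.14 (adjusted p = 4.03e-07), Sqle at 2.06 ± 0.19, Cyp51 at 1.93 ± 0.23, Hmgcs1 at 1.70 ± 0.19 and Lss at 1.37. Other metabolic lists that rose were the integrated stress response (10 higher, 1 lower, median 1.51, 0.00196; 0.281 with an estimated correlation; Mthfd2 2.34 ± 0.14, Asns 4.81 ± 0.35) and oxidative phosphorylation (16 of 25 higher, median 0.59, 0.000308; 0.444 with an estimated correlation; Sdhb 1.00 ± 0.17). Glycolysis rose (10 higher, 2 lower, median 1.03, 0.0134; 0.469 with an estimated correlation; Tpi1 1.88, Slc2a3 -1.06), a call lost without WT FoB 1 (0.0576). DNA repair genes rose (18 of 23, median 1.33, 8.64e-08; 0.205 with an estimated correlation; Msh6 2.36 ± 0.14). Interferon-stimulated genes fell (21 of 22 lower, median -1.85, 1.8e-09; 0.101 with an estimated correlation; Zbp1 -1.93 ± 0.15, Ifit3 -3.21 ± 0.30), as did MHC class II genes (11 of 12, median -1.11, 0.000153; 0.281 with an estimated correlation; H2-Oa -2.17 ± 0.22, H2-Aa -1.44 ± 0.25). Ribosomal proteins were lower (10 of 28, median -0.51, 0.00416; 0.580 with an estimated correlation; Rps14 -1.08 ± 0.23), a call lost without WT GCB 1 (0.0536). Immediate early genes were lower (1 higher, 10 lower, median -1.43, 0.00371; 0.315 with an estimated correlation; Ier5 -2.53 ± 0.21, while the chaperone Hsp90aa1 rose by 1.72).

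IRF and ETS factors were lower in WT GCB (1 higher, 8 lower, median -0.49, camera adjusted p = 0.0413; 0.355 with an estimated correlation; Irf4 -2.28). That call was lost with the block (0.0543; 0.0163 to 0.454 over 10 alternatives), and without WT FoB 2 (0.0605), WT FoB 3 (0.0788) or WT GCB 1 (0.0832). Markers of other cells were also lower in GCB than in FoB. NK genes had 9 of 9 lower (median -2.44, 0.0015; 0.355 with an estimated correlation; Prf1 -1.76), T cell genes 1 higher and 10 lower (median -1.27, 0.0134; 0.444 with an estimated correlation; Cd2 -1.65 ± 0.15) and marginal zone and B-1 genes 1 higher and 7 lower (median -1.02, 0.0106; 0.315 with an estimated correlation; Plac8 -4.46 ± 0.41). The T cell call was lost without WT FoB 2 (0.0578). Not past were LXR targets (0.0806, though Abcg1 fell by 3.66 and Abca1 by 2.17), fatty acid synthesis (0.126, Fads2 5.81 ± 0.40, Scd1 -1.41), plasma cell (0.2), positioning (0.286, 8 higher and 13 lower, median 0.06, mean -0.31, test lower), ribosome biogenesis (0.119) and B cell receptor signaling (0.131). Also not past were sterol sensing (0.547), SRF targets (0.193), apoptosis (0.27), dendritic cell (0.144), neutrophil (0.405) and erythroid genes (0.709). Macrophage genes (0.447, median 0.15, mean -0.24) and mitochondrially encoded genes (0.963, median 0.19, test lower) did not pass either.

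In cKO the contrast of GCB with FoB gave the same direction for the main lists. Cholesterol genes had 15 higher and 1 lower (median 1.08, camera adjusted p = 0.000194; 0.229 with an estimated correlation), all 14 naive genes fell (median -2.72, 9.76e-10; 0.229 with an estimated correlation) and germinal center genes had 15 higher and 2 lower (median 4.83, 7.1e-08; 0.0970 with an estimated correlation). Plasma cell genes passed here (10 higher, 3 lower, 0.0378; 0.437 with an estimated correlation), a call lost without cKO GCB 2 (0.0625). Ribosome biogenesis (9 higher, 0.0175; 0.315 with an estimated correlation) and B cell receptor signaling (2 higher, 10 lower, 0.0203; 0.315 with an estimated correlation) passed as well. T cell (0.321) and marginal zone genes (0.255) did not, and memory genes (0.0378) lost the call with the block (0.0874; 0.0181 to 0.467 over 10 alternatives). Their adjusted p was 0.375 with an estimated correlation.

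The difference of genotype effects tested whether cKO acted otherwise in GCB than in FoB. Dglucy was the 1 gene past the edgeR test: its log2 fold change was 3.40 ± 0.27 higher in GCB (adjusted p = 0.000467), and all 16 alternatives kept it (6.1e-23 to 0.00411). WT GCB held 24, 16 and 19 counts of Dglucy and cKO GCB 314, 249 and 242, while FoB held 16.5 CPM in WT and 20.4 CPM in cKO. The count at an unadjusted p under 0.05 was 371. With the block 36 genes were past, all higher in GCB, among them the p53 target Ccng1 (1.03 ± 0.12), Pdlim1 (1.21 ± 0.15), Csf1 (1.75 ± 0.22), Serpine2 (3.05 ± 0.39) and Il9r (1.23 ± 0.16). These 5 had an adjusted p of 0.00681 with the block, and up to 1.00, 1.00, 0.837, 0.360 and 1.00 over their alternatives. Across genes the genotype effects in GCB and FoB correlated weakly (Pearson 0.120, Spearman 0.141).

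The cholesterol list differed between the cell types (21 of 22 below 0, median -0.26, camera adjusted p = 3.93e-06; 0.197 with an estimated correlation). The naive (median 0.76, 9.96e-10; 0.197 with an estimated correlation), memory (0.96, 6.98e-08; 0.197), T cell (1.02, 3.23e-06; 0.308) and plasma cell lists (0.35, 1.21e-05; 0.197) had higher effects in GCB than in FoB. So had the marginal zone and B-1 (0.67, 1.21e-05; 0.197 with an estimated correlation) and positioning lists (0.19, 1.21e-05; 0.197), the positioning list with opposite signs (lower in FoB). The NK list passed (0.72, 0.0223; 0.771 with an estimated correlation) but was lost without WT FoB 2 (0.552), cKO FoB 1 (0.532), cKO FoB 3 (0.121), WT GCB 1 (0.05002), WT GCB 3 (0.212), cKO GCB 2 (0.126) or cKO GCB 3 (0.0571). The light zone list passed (0.26, 0.0262; 0.576 with an estimated correlation) but was lost without WT FoB 2 (0.0617), WT FoB 3 (0.145), cKO FoB 1 (0.164), cKO FoB 2 (0.168), WT GCB 1 (0.353), WT GCB 2 (0.0869), cKO GCB 1 (0.152) or cKO GCB 3 (0.0984). B cell receptor signaling passed as lower (-0.09, 0.0262; 0.518 with an estimated correlation) but was lost without WT FoB 1 (0.295), cKO FoB 2 (0.176), cKO FoB 3 (0.144), WT GCB 2 (0.0528), WT GCB 3 (0.262), cKO GCB 2 (0.133) or cKO GCB 3 (0.0552). Adjusted over the list alone, 0 cholesterol, 4 naive and 5 positioning genes were past. With the block glycolysis (0.0259; 0.666 with an estimated correlation) and ribosome biogenesis (0.0158; 0.736) passed as well.

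The authors' deposited table of results gives the same comparisons from their own edgeR run. Its false discovery rate was under 0.05 for 31 genes in GCB, 30 higher and 1 lower, and all 31 were past the fit with the replicate block, against 13 without it. The lower one was the immunoglobulin segment Ighv1-67 (-1.16, false discovery rate 0.0413). In FoB it had 0 such genes (smallest false discovery rate 1.00). In that table Rock2 stood at -0.51 (0.425), Hmgcs1 at -0.57 (0.0895), Cdkn1a at 2.71 (0.00099) and Phlda3 at 3.83 (0.000739). Across genes the authors' and the present log2 fold changes in GCB correlated at 0.996.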

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

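All results in this part come from comparisons and lists fixed before the data were examined, and no test here was chosen after the result was seen.

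The genotype effect differed between GCB and FoB beyond its test for Dglucy, with a log2 difference of 3.40 (GCB minus FoB). It also differed for 10 gene lists, given here as the median log2 difference of effects. Naive follicular genes (0.76), memory precursor genes (0.96) and plasma cell genes (0.35) had higher effects in GCB than in FoB. So had the marker lists of T cells (1.02), NK cells (0.72) and marginal zone and B-1 cells (0.67), and the positioning (0.19) and light zone lists (0.26). The positioning list was lower in cKO FoB (adjusted p = 0.00544) and in GCB was lost with the block (0.100), so its difference does not rest on a rise in GCB alone. Cholesterol synthesis genes (-0.26) and B cell receptor signaling genes (-0.092) had lower effects in GCB than in FoB. For all 10 lists the call was made with the preset correlation, and with an estimated correlation 0 lists passed. The naive, memory, positioning, T cell and marginal zone lists share genes such as Ccr6, Bcl2 and Cd5, so they are not separate results.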

How the results depend on the processing

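Tests with the block in DESeq2, limma-voom or beside an estimated correlation, and block fits without a library, were chosen after the result was seen, and the others were planned.

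In cKO GCB the count of called genes, 14 at first, depended on the test. It was 62 with no filter, 130 with DESeq2, 121 with the likelihood ratio test, 5 with only the groups compared and 5 at an adjusted p under 0.01. Leaving out 1 library gave 5 to 58, with 58 only without cKO GCB 3. The cause was not tested. With the replicate block it was 293, all 14 among them, and with block and DESeq2 551, with block and limma-voom 312, and with the block but without cKO GCB 1 135 (129 higher and 6 lower).

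In FoB, where 0 genes were called, no filter gave 5, DESeq2 4 and the likelihood ratio test 6. The block gave 7 with DESeq2, 2 with limma-voom and 1 in edgeR without WT FoB 1. The cell type counts were 4206 in WT and 3978 in cKO at an absolute log2 fold change of at least 1. The difference of genotype effects gave 2 genes with no filter, 21 with DESeq2, 15 with the likelihood ratio test and 36 with the block.

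With the block Rock2 in GCB stood at -0.53 and passed. Beyond the counts, Rock2 in GCB, Rock1 between cell types and the list calls given in the report, the block changed no other call of a named gene or list that passed without it. Without 1 library Rock2 ran from -0.65 to -0.39 in GCB and from -0.58 to -0.32 in FoB, never past the test.

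List calls rested on the preset correlation. With an estimated correlation 0 lists passed in each of the 5 comparisons, and with the block and an estimated correlation also 0. That held even between cell types in WT, where 20 lists passed with the preset correlation and the smallest adjusted p with an estimated one was 0.101. Failing to pass with an estimated correlation therefore does not show that a list is unchanged. With fry 0 lists passed in GCB, FoB and the difference, while 28 passed between cell types in WT and 26 in cKO. In FoB the number of lists past camera ran from 3 without cKO FoB 3 to 13 without WT FoB 1. The S phase list in FoB reversed without WT FoB 1 (adjusted p 0.328, and 0.000314 to 0.328 over the libraries left out). The G2/M list reversed without WT FoB 1 (2.97e-06) and without cKO FoB 2 (0.407), and ran from 1.11e-08 to 0.407.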

Other observations

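Of the tests of explanations in this part, only the splits of the difference of genotype effects were written before the result was seen. The other tests of explanations, the p53 list among them, were chosen after it. The camera tests of the lists fixed earlier, repeated here, were planned.

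In these libraries the cKO GCB carried more RNA of Cdkn1a, Phlda3 and Zmat3, and with the block also of Ccng1, Bax, Bbc3, Sesn2 and the receptors Gpr183, Ccr6 and Il9r. Over the alternatives Ccng1 passed in 7 of 20, Bax in 4 of 20 (adjusted p up to 0.947), Bbc3 in 4 of 19 and Sesn2 in 3 of 20 (both up to 1). Most of these alternatives leave out the block, so the calls rest largely on it and are weak without it. Gpr183, Ccr6 and Il9r passed in 11, 10 and 7 of 20. The apoptosis and integrated stress response lists did not pass (adjusted p = 0.414 and 0.843). Of 22 cholesterol synthesis genes 21 lay below 0, none past the test singly without the block, with an adjusted p of 0.156 for the list with an estimated correlation. In FoB neither the cholesterol nor the naive list passed its test.

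Several genes higher in cKO GCB are p53 targets, so a list of such targets was tested without Cdkn1a, Phlda3, Zmat3 and Ccng1, which prompted it. The remaining 29 genes were higher as a group (24 above 0, median 0.21, camera p = 0.00213 with an estimated correlation), but Bax, Bbc3 and Sesn2, also seen before, were among them. The 26 without them gave 0.00561 (limma camera p with an estimated correlation, 21 above 0). The 22 on no list fixed earlier gave 0.00555 by the same test (18 above 0). Not all members moved alike: of the 29, Mdm2 stood at 0.08 ± 0.15 and Fas, the lowest, at -0.40 ± 0.20 in GCB. Singly, 0 of the 29 passed edgeR without the block, and with it 7 rose and 0 fell. Both the 26 and the 22 kept Tnfrsf10b, Ei24, Aen and Ddit4, which had passed edgeR with the block (adjusted p 0.00997, 0.0243, 0.0436 and 0.0129). The list was written after the results were seen, so these tests are not independent of them. Their p-values are unadjusted, unlike those of the other lists, which were adjusted over 35 lists. Higher p53 activity stays as a hypothesis. In cKO FoB, where Cre is also present, the median of the 29 was 0.0709 (limma camera p = 0.178 with an estimated correlation). The 29 leave out the genes that prompted the list. Among those, Cdkn1a measured 0.96 ± 0.20 CPM in WT FoB and 1.75 ± 0.17 CPM in cKO FoB. Phlda3 measured 0.37 ± 0.12 and 0.65 ± 0.07 CPM, and Ccng1 108 ± 21.3 and 113 ± 35.5 CPM. None of these passed edgeR in FoB, so a smaller rise there is not excluded. Since Cre and Rock2 loss coincide in each cKO mouse, either may be the source of the higher p53 targets. RNA of FoB cells in the GCB libraries cannot account for all called genes, since 7 of 14 lay above every FoB library and the share needed for the other 7 ran from 12.8% for Aff1 to 119% for Csf1.

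The naive genes higher in cKO GCB may reflect FoB RNA, since both cell types were sorted from spleen and a sort can leave some FoB behind. The FoB share was taken relative to the WT GCB library of the same number, so FoB RNA that WT GCB itself holds is not counted. From 100 FoB-restricted genes outside the list, this share of cKO GCB came to 9.84%, 4.08% and 1.93% in numbers 1, 2 and 3. Quartiles over these genes were 5.09% to 14.0%, 2.43% to 6.90% and 0.116% to 3.68%. Taking the shares off left median excesses of 0.12, 0.0258 and 0.12. A rise of FoB genes within cKO GCB cells would raise these shares too, so the correction cannot tell it from FoB RNA. The memory genes kept 0.67, 0.28 and 0.43 of 1.25, 0.80 and 0.71, above 0.2 in each number, so these shares do not take off their excess. Ighd gave smaller shares (3.52%, 0.669% and 0.737%) and would leave 0.88, 0.50 and 0.29, while Gpr183 would need 23.3%, 14.1% and 9.58%. Library cKO GCB 1 alone is not the cause, since the lower of the medians of the other numbers was 0.447.

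The lower cholesterol genes could in part come from the same FoB RNA, which holds less of them. The shares above would give medians of -0.09, -0.04 and -0.02, against -0.41, -0.33 and -0.25 measured, a gap of at least -0.230 on the log2 scale in each number. FoB RNA at these shares is thus too little. A lower synthesis program in cKO GCB stays as a hypothesis. With an estimated correlation the list had a camera adjusted p of 0.156, but that setting passed 0 lists between cell types too. Cre activity and a change in the mix of germinal center cells were not tested and stay open.

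The germinal center genes lower in cKO FoB may reflect GCB RNA in the WT FoB libraries. The GCB share came to 3.04%, 0.229% and -0.506%, and taking it off left medians of 0.45, 0.00476 and -0.191 and means of 1.27, 0.32 and -0.70. The lowest median lay near the bound of -0.2 and the lowest mean far under it, so GCB RNA stays open as the cause. Each share was taken relative to the cKO FoB library of the same number. A negative share thus means that WT FoB 3 held no more of the GCB-restricted genes than cKO FoB 3 at the median. The quartiles of that share (-0.882% to 0.258%) spanned 0, so its sign is uncertain. The lower median of numbers 2 and 3 was -0.207, which leaves open how much WT FoB 1 decides.

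For GCB, 1 of the 10 splits of the 6 libraries called as many genes as the real 14, the real one, and the highest other called 0. For FoB 10 of 10 splits called at least the real 0, and the highest other called 1. Between cell types 1 of 10 splits reached the real 6634 in WT and 1 of 10 the real 6384 in cKO, and the highest other called 0 in both. With 10 splits the share cannot fall under 0.05. For the difference of genotype effects, 15 of 100 splits drawn from 200 called at least 1 gene, as many as the real split, so chance is not excluded for the count. The highest other called 1872, which points to a structure of the samples: that split parts 2 of the 6 pairs of the same number, and the real split parts all 6. Among the 17 splits that part all pairs the highest other called 7.

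Gm12666, a pseudogene, had 14, 11 and 29 counts in the cKO FoB libraries and 36, 45 and 100 in cKO GCB, against 0 in each WT FoB library and 0, 1 and 0 in WT GCB. The naming rule picked it in FoB, and in GCB it was looked at after its values were seen.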
